A study of Mus musculus with 8 samples.

How the data were processed

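Total RNA of mouse germinal vesicle (GV) stage oocytes, the immature oocytes whose nucleus is still intact, was hybridised to 8 single-colour Affymetrix mouse arrays. Per the labels, 4 samples were untreated GV oocytes and 4 were GV oocytes cultured for 48 h in milrinone, and 15 µg of biotinylated cRNA went onto each array. No label gives a sample cultured without milrinone, so the drug, the culture and the elapsed time cannot be told apart. The equal mass of cRNA means that a level is relative to the rest of the RNA in its sample. Nothing in the labels says whether replicates came from separate animals or collections, so p-values measure the spread between these samples, which may be technical.

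The values are the deposited intensity of each of 45101 probe sets on a linear scale, which the authors made from the scanned arrays. The software, the scaling target and the rule that left cells empty are not given in the sources used here. Between 48.4% and 58.1% of the cells of an untreated array and between 56.9% and 58.7% of those of a milrinone array were empty. A probe set with a value on an array is called listed there. An empty cell sets no upper limit on the signal, so no fold is given for a probe set listed in only 1 of the groups. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.17.

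Gene names come from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq table of the mouse assembly. Of 45037 probe sets that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in that annotation. The update matched 34741 of the 34945 and kept the older symbol for the other 204. No change is assigned to a single gene from a probe set with several symbols. No genome sequence was used, so no coordinates are given.

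Intensities were analysed as log2(intensity + 16), and every log2 difference is milrinone minus untreated on that scale, which understates changes of dim probe sets. Empty cells were left out of the fit. Probe sets listed on at least 3 of 4 arrays in each group were tested, 16288 in all, which stand for 9454 genes with 1 symbol. All 16288 also passed the filter chosen before the data were examined, a mean at or above the median of all probe sets. The rule on listing was made after the empty cells were seen and before any difference was computed. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

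The deposited scaling was kept. The rule set beforehand was to keep it if the 2% trimmed means of the arrays lay within 10% of their mean, and otherwise to use quantile normalization. Over the listed values of each array the trimmed means lay between -17.9% and 7.16% of their mean, which fails that rule. Over the probe sets listed on all 8 arrays they lay between -4.82% and 2.20%, and with empty cells counted as 0 between -2.54% and 2.94%, which passes it. The choice between these readings was made after the empty cells were seen. Quantile normalization gave 18 changed probe sets, 17 of them among the 19 found with the deposited scaling.

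A set of 15 gene lists was fixed before the data were examined, and 12 of them had at least 5 tested genes. Lists were tested with camera in limma at a preset correlation of 0.01, using the brightest tested probe set of each gene and only genes listed on all 8 arrays, 8508 in total. Camera with an estimated correlation and fry were run beside it. Exact permutation tests of 4 against 4 arrays are two-sided, and the smallest p they can give is 0.0286. The retrotransposon list took gene names by a pattern, and 10 of its 11 matches were unrelated genes that shared a name fragment and were left out by hand.

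The genes named were chosen by a rule fixed beforehand. It takes up to 12 rising and 12 falling genes with non-overlapping groups and the largest change, up to 4 tested members of each list with the smallest adjusted p, and Pde3a, Gdf9, Zp3, Mos, Plat, Ccnb1, Actb, Gapdh, Hprt and Dicer1. Ccnb1 and Gapdh had no probe set with a single symbol. Genes listed mainly in 1 group, the untested marker genes given with their values, and the repeat control probe sets were picked after their values were seen.

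On data simulated for this comparison from the means, spreads and empty cells of the 16288 probe sets, with 200 changed, the limma test recovered 68% of those changed 2-fold, 96% at 4-fold, 100% at 8-fold and 98% at 16-fold, and 14 of its 195 calls were false. The simulated noise was independent between probe sets. In a second simulation on 8508 genes, camera in limma gave an unadjusted p of 0.989 for an unshifted list of 40 genes and 2.2e-129 for a list of 40 shifted by 0.5. Its noise was also independent between genes, so it does not show how often camera makes false calls on correlated genes. The alternatives tried were other pseudocounts, scalings, filters, thresholds, spread models and probe set choices, the replicate number as a block, and leaving out each array in turn. Another 3 were chosen after seeing the data, namely leaving out untreated arrays 1 and 4, using only probe sets listed on all 8 arrays, and setting empty cells to 0. Centring on poly-A spike controls was not run, because nearly all of those cells were empty.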

Results

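Untreated mouse GV oocytes were compared with separate samples of GV oocytes cultured for 48 h in milrinone, an inhibitor of the phosphodiesterase encoded by Pde3a that keeps oocytes arrested at the GV stage. The series title places the question in the stability of abundant retrotransposon transcripts. The untreated arrays listed 23269, 21184, 20007 and 18888 probe sets for replicates 1 to 4, and the milrinone arrays listed 18605, 18836, 18731 and 19448 (exact permutation p = 0.0571). Untreated 1 stood apart, with a median correlation of 0.930 with the other arrays against 0.966 to 0.980 for the other 7. It also had the lowest score on the first principal component, at -59.8, and untreated 4 had the highest on the second, at 40.4. The ratio of 3' to 5' signal of the Actb control, a measure of RNA integrity and amplification, ran from 6.87 to 13.1 in untreated and from 11.6 to 20.4 in milrinone samples (exact permutation p = 0.0571). That of the Gapdh control ran from 6.23 to 7.68 and from 6.09 to 8.25 (exact permutation p = 0.771).

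In the samples cultured for 48 h in milrinone, 19 probe sets were lower than in the untreated samples and 0 were higher (limma, adjusted p under 0.05). A lower level there is called a fall, and the 19 probe sets named 12 genes. The largest falls were in Gja1, the gap junction protein connexin of granulosa cells, which fell by 4.91 on the log2 scale (SE 0.60, adjusted p = 0.0109), and in Grem1, a secreted BMP antagonist made by cumulus cells, which fell by 4.67 (SE 0.47, adjusted p = 0.00482). The nuclear noncoding RNA Malat1 fell by 3.94, the lysosomal protease gene Ctsl fell by 3.90 and Kctd14 fell by 3.24. Pde7b, which encodes a phosphodiesterase specific for cAMP, fell by 2.78 (SE 0.24, adjusted p = 0.00338), from an intensity of 779 ± 235 (SD, n = 4) to 96.1 ± 6.51 (SD, n = 3). Markers of granulosa, cumulus and theca cells filled 27 to 42 of 60 probe sets on the untreated arrays and 11 to 18 on the milrinone arrays, the most on untreated 1.

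The other genes that fell were Tmx1 and Pdia6, which encode thiol oxidoreductases of the endoplasmic reticulum, Synpo, which encodes an actin-associated protein, Dsp, which encodes the desmosome protein desmoplakin, and the transcriptional regulators Zeb1 and Myocd. Tmx1 fell by 3.13, Synpo fell by 2.67, Dsp fell by 2.39, Zeb1 fell by 2.09, Myocd fell by 2.05 and Pdia6 fell by 1.46 on the log2 scale, with adjusted p from 0.00437 for Zeb1 and Myocd to 0.0477 for Tmx1. A second probe set of Dsp fell by 2.28 (SE 0.14, adjusted p = 0.000114), the smallest p of the 19. The 19 also held another probe set of Malat1, and 3 of Gja1 in all, which is no separate check because all 19 fell. Another probe set of Kctd14 was listed at 346 ± 39.0 (SD, n = 4) on the untreated arrays and was empty on the milrinone arrays, whereas a dimmer probe set of Pdia6 differed by 0.11 and did not pass. The remaining 3 of the 19 probe sets had several gene symbols or none. At an unadjusted p under 0.05 there were 1568 probe sets, 916 higher and 652 lower in milrinone, where chance alone gives 814.4 and another split of the 8 arrays into 4 and 4 gave 1994. The absence of adjusted rises does not show that none occurred. Leaving out untreated 1 gave 69 changed probe sets, 68 of them falling and including all 19, and leaving out milrinone 3 gave 9. Leaving out milrinone 3 took the probe sets with the largest fall of Gja1 to an adjusted p of 0.0527, of Malat1 to 0.0859 and of Dsp to 0.143, and Ctsl to 0.0676, Tmx1 to 0.193 and Pdia6 to 0.160, and these probe sets of Malat1 and Dsp, with Ctsl, Tmx1 and Pdia6, also missed the threshold without at least 1 other array. A second probe set of Gja1 and the second of Dsp passed under each of the 21 alternatives that gave them a value, and the remaining one of Gja1 under 16 of 20.

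**Figure D1:**
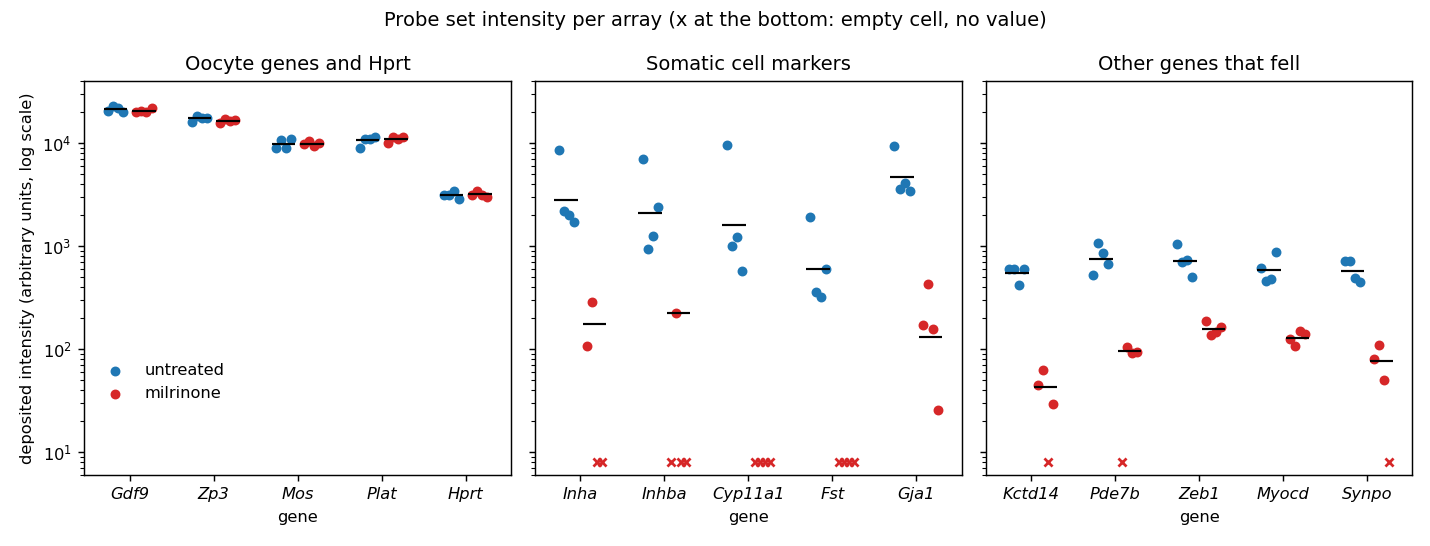
Deposited intensity (log axis) of each array for oocyte genes with Hprt, markers of granulosa and theca cells, and other genes that fell, with untreated samples in blue and milrinone samples in red. Points are arrays, short bars are geometric means of the listed values, and x marks empty cells, which have no value; Gdf9, Zp3, Mos, Plat and Hprt overlap between the groups, and the probe sets drawn for Cyp11a1 and Fst are empty on the milrinone arrays.

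No gene of the oocyte-specific and maternal-effect list was detected to change. Of its 46 tested genes, 0 passed the limma test, also adjusted over the list alone, 0 had an unadjusted p under 0.05, and their median log2 difference was 0.01. Gdf9, a growth factor secreted by the oocyte, differed by -0.05 (95% interval -0.16 to 0.07), and Zp3, a protein of the zona pellucida, by -0.07 (-0.19 to 0.05). Gdf9 had 20134 to 22872 on the 8 arrays, near the highest listed values of 23742 to 24974, so its narrow interval does not show that its level was stable. Pou5f1 differed by 0.25, Brwd1 by 0.26, Astl by -0.21 and Khdc3 by -0.54, with adjusted p from 0.545 to 0.558. Of the 19 tested messages known to be stored and recruited at maturation, 0 passed and 1 had an unadjusted p under 0.05 (limma), with a median of 0.04. Among them Mos, a kinase that activates the MAP kinase pathway in meiosis, differed by 0.01 (-0.18 to 0.19), Plat by 0.05 (-0.14 to 0.24), Dcp2 by 0.29 (a second probe set by -1.04, adjusted p = 0.495), Cnot7 by 0.09, Tpx2 by 0.15 and Hprt by 0.02. Actb, a common reference gene, differed by -0.84 (-1.42 to -0.25, adjusted p = 0.460). It had 15514 on untreated 1, 5556 to 9467 on the other untreated arrays and 4339 to 4917 in milrinone. Centring the arrays on ribosomal proteins moved the median of all tested probe sets from 0.06 to 0.30 and gave 0.18 for Gdf9, 0.16 for Zp3 and 0.02 for Astl. Centring on the median gave -0.02 for Mos, -0.01 for Hprt and -0.02 for the oocyte list. The oocyte list as a whole did not pass (camera adjusted p = 0.387), but it passed with array weights (adjusted p = 0.0479) and, in an alternative chosen after seeing the data, without untreated 1 and 4 (median -0.08, adjusted p = 0.0107), in a range of 0.0107 to 0.907 over the alternatives.

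Markers of cumulus, granulosa and theca cells were listed mainly on the untreated arrays. Of 60 probe sets of that list, the untreated arrays listed 42, 34, 30 and 27 for replicates 1 to 4 and the milrinone arrays 17, 18, 13 and 11 (exact permutation p = 0.0286, the smallest this design allows, and 0.143 after adjustment over 15 lists). The steroidogenic gene Hsd3b1 had intensities of 15428, 3688, 4335 and 2116 on the untreated arrays and was listed on 2 of 4 milrinone arrays at 224 and 165. The inhibin subunit genes Inha and Inhba had 8512 and 6953 on untreated 1. Cyp11a1, which encodes the side chain cleavage enzyme of steroid synthesis, had 9664 on untreated 1 and 576 to 1209 on the other untreated arrays, and no value in milrinone, although another of its probe sets was listed at 207 ± 18.9 (SD, n = 4) there. Of the 27 genes of the list on the array, 10 were listed on all 4 untreated and at most 2 milrinone arrays, and 2 on all 8. Among the 6 tested genes Gja1 fell, Hsd17b1 differed by -2.48, Foxl2 by -1.86 and Nr5a2 by -0.62, and 3 genes fell when adjusted over the list alone. Without untreated 1, Hsd17b1 (-1.70, adjusted p = 0.0488) and Foxl2 (-1.14, adjusted p = 0.0426) also passed. Nr5a2 had 3223 on untreated 1, 1125 to 1494 on the other untreated arrays and 836 to 1193 in milrinone, so its difference leaned on that array.

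Markers of blood, stromal and endothelial cells were also listed less often on the milrinone arrays. Of 29 probe sets, 19, 13, 16 and 11 were listed on the untreated arrays and 4, 5, 4 and 4 on the milrinone arrays (exact permutation p = 0.0286, adjusted p = 0.143 over 15 lists). The collagen gene Col1a2 had 2550 on untreated 1 and 205 to 343 on the other untreated arrays, with no value in milrinone. Lyz2, a lysozyme gene of macrophages, was highest on untreated 3, at 740. The 3 tested genes, Cd68, Kdr and Tek, did not pass, with differences of -0.34, -0.15 and 0.12, and 0 had an unadjusted p under 0.05 (limma). Centring on ribosomal proteins gave 0.08 for Kdr.

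In the cAMP and phosphodiesterase list 1 of 26 tested genes, Pde7b, fell, also adjusted over the list alone, and 25 did not pass. Prkar2b and Prkacb, subunits of the cAMP-dependent protein kinase, differed by -1.13 and -0.50 and the kinase inhibitor gene Pkig by 0.27. Without untreated 1 the difference of Prkar2b was -0.65. Prkar1b, a regulatory subunit of the same kinase, was listed at 324 ± 28.9 (SD, n = 4) on the untreated arrays and on 0 of 4 milrinone arrays with its brightest probe set. A dimmer probe set of Prkar1b was listed on 3 untreated arrays at 111 ± 5.66 (SD, n = 3) and on 2 milrinone arrays at 115 ± 15.4 (SD, n = 2). Pde3a, whose product milrinone inhibits, was not tested. Its brightest probe set was listed on 1 untreated array at 174 and on 3 milrinone arrays at 274 ± 33.3 (SD, n = 3). The list as a set did not pass (camera adjusted p = 0.126). Pde7b was empty on milrinone 1, so it was not among the 21 genes behind this camera p. The list passed under 4 of 25 alternatives, over a range of adjusted p from 0.0202 to 0.281. Those values were 0.0306 without untreated 4, 0.0202 without milrinone 1, 0.0389 without untreated 1 and 4 and 0.0446 with empty cells at 0.

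Camera called 2 of 12 lists, both lower in milrinone relative to the other genes. Cytosolic ribosomal protein genes had a median of -0.16 (adjusted p = 1.2e-10), or 0.07 when the arrays were centred on this list, and 40 of 46 tested genes were lower while 0 passed singly and 12 had an unadjusted p under 0.05 (limma). With an estimated correlation the adjusted p = 0.561. The 2 called probe sets with Rpl9 among several symbols were not counted in this list. Rps3 differed by -0.67, Rps3a1 by -0.82, Rpsa by -0.77 and Rps9 by -0.57, and all 4 of these genes were highest on untreated 1. Without untreated 1 the median was -0.03 (adjusted p = 0.00516, in a range of 2.5e-14 to 0.0107 over the alternatives). The stress response list had a median of -0.04 and a mean of -0.20 (adjusted p = 0.00106, and adjusted p = 0.0639 with an estimated correlation), its median becoming 0.19 with centring on ribosomal proteins, and 0 of 32 genes passed, with 7 at an unadjusted p under 0.05 (limma). Its members with the smallest p were the unfolded protein response regulator Xbp1 at -2.26 (without untreated 1 -1.70, adjusted p = 0.0241), the chaperone genes Hspa5 at -0.49, Hspd1 at -0.62 and Hsp90b1 at -0.56. Xbp1 was empty on milrinone 3, so it was not among the 30 genes behind the median, the mean and the camera p of this list. Fry called 0 of 12 lists, with 1 at an unadjusted p under 0.05. Leaving out untreated 2, untreated 4, milrinone 1 and milrinone 2 gave 4, 4, 4 and 5 called lists. Among the 35 splits of the 8 arrays into 4 and 4, 30 called at least 2 lists, so the number of called lists was within what regrouped arrays gave.

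**Figure D2:**
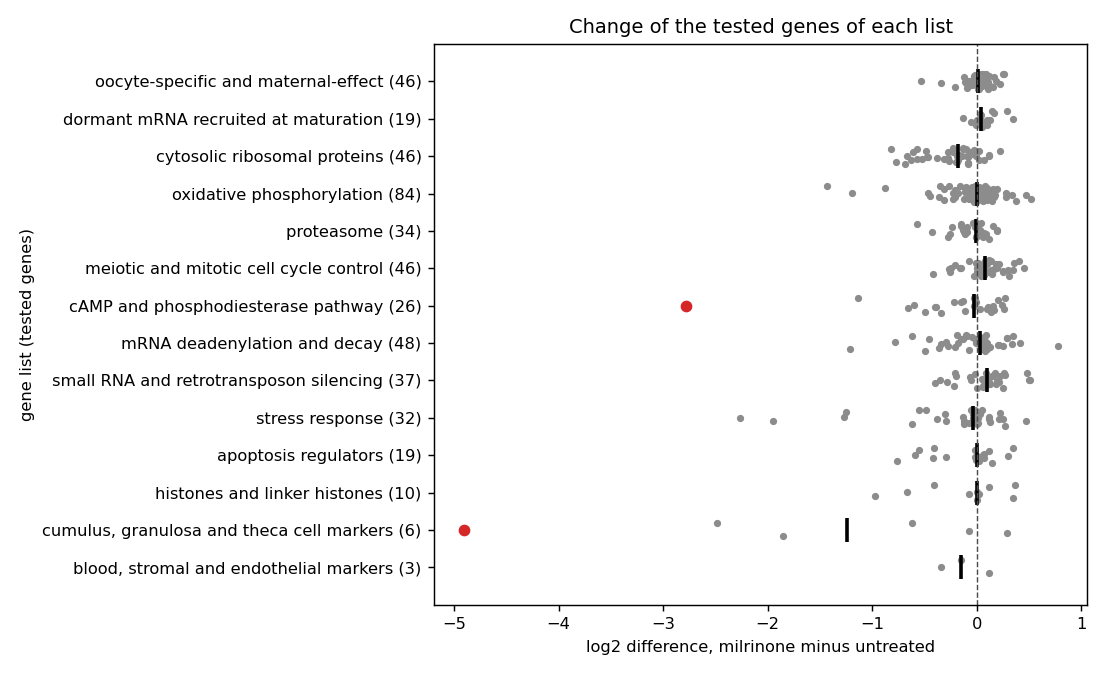
Log2 difference (horizontal axis, milrinone minus untreated) of each tested gene, by gene list with the number of tested genes. Grey points are genes, black bars are medians and red points are genes that passed the test, namely Pde7b and Gja1.

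The other lists did not pass. Their medians and adjusted p were 0.01 and 0.126 for oxidative phosphorylation, -0.01 and 0.126 for the proteasome, 0.07 and 0.387 for cell cycle control, 0.03 and 0.387 for mRNA decay, 0.09 and 0.436 for small RNA and retrotransposon silencing, 0.01 and 0.212 for apoptosis regulators, and 0.00 and 0.212 for histones. In the oocyte, oxidative phosphorylation, mRNA decay, apoptosis and histone lists the median lay above 0 and the test pointed down. Camera compares a list with the other genes, and the median of all tested probe sets was 0.06. Its direction is thus relative to those genes and not to 0. Centring on the median gave -0.02 for oxidative phosphorylation, -0.02 for apoptosis and -0.03 for histones, and centring on ribosomal proteins gave 0.22 for the proteasome. Without untreated 2 and without milrinone 2, oxidative phosphorylation and the proteasome passed, and oxidative phosphorylation also passed without untreated 3, untreated 4 or milrinone 1, and histones without milrinone 2. No gene of these lists passed (limma), and 10 of 84 oxidative phosphorylation genes and 7 of 48 mRNA decay genes had an unadjusted p under 0.05. For oxidative phosphorylation Atp5g3 differed by -1.19, Uqcrb by -0.26, Cox6b2 by 0.52 and Uqcrc1 by -1.43. Atp5g3 had 11370 on untreated 1, 3352 to 4504 on the other untreated arrays and 1960 to 2627 in milrinone. Uqcrc1 had 1078, 209 to 380 and 89.5 to 189, so both differences leaned in part on untreated 1. Among proteasome genes Psma6 differed by 0.19 and Psmb5 by -0.57, and among cell cycle genes Stag3 by 0.45, Sgo1 by 0.40, Pttg1 by -0.42 and Incenp by 0.13. Cnot4 and Cnot6, which encode proteins linked to the CCR4-NOT complex, differed by 0.42 and -0.62, Pan2 by 0.35 and Zfp36l1 by -1.21 (-0.75 without untreated 1). Of the silencing genes, Ago3 differed by 0.51, Mael by 0.49, Tarbp2 by 0.26, Dnmt1 by -0.22 and Dicer1 by -0.06. Centring on ribosomal proteins gave 0.01 for Dnmt1 and 0.17 for Dicer1. Bcl2l1 differed by 0.34, Mcl1 by -0.77, Birc2 by -0.59 and Casp9 by -0.40, and the histone genes H2az1 by -0.67 and H1f10 by 0.36.

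Retrotransposon transcripts could be followed only in part, because the annotation used here named 1 such gene, Erv3, which was listed on 1 of 8 arrays. The 3 control probe sets whose identifiers name the B1 and B2 short interspersed repeats were examined after their values were seen. The dimmer B2 probe set had 376 ± 44.1 (SD, n = 4) in untreated and 673 ± 108 (SD, n = 4) in milrinone samples, a difference of 0.81 (95% interval 0.44 to 1.17). The brighter B2 probe set had 19736 ± 362 (SD, n = 4) and 22476 ± 541 (SD, n = 4), a difference of 0.19 (0.10 to 0.28). Each was higher on all 4 milrinone arrays than on any untreated array (exact permutation p = 0.0286, adjusted p = 0.0429 over 3 probe sets), but neither passed among all tested probe sets (limma adjusted p = 0.178 and 0.223). The B1 probe set differed by 0.27 (-0.03 to 0.57, exact permutation p = 0.0857). Centring on ribosomal proteins gave 0.50 for B1, 0.42 for the brighter B2 and 1.04 for the dimmer B2 probe set. Centring on the median gave 0.24, 0.16 and 0.78.

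**Figure D3:**
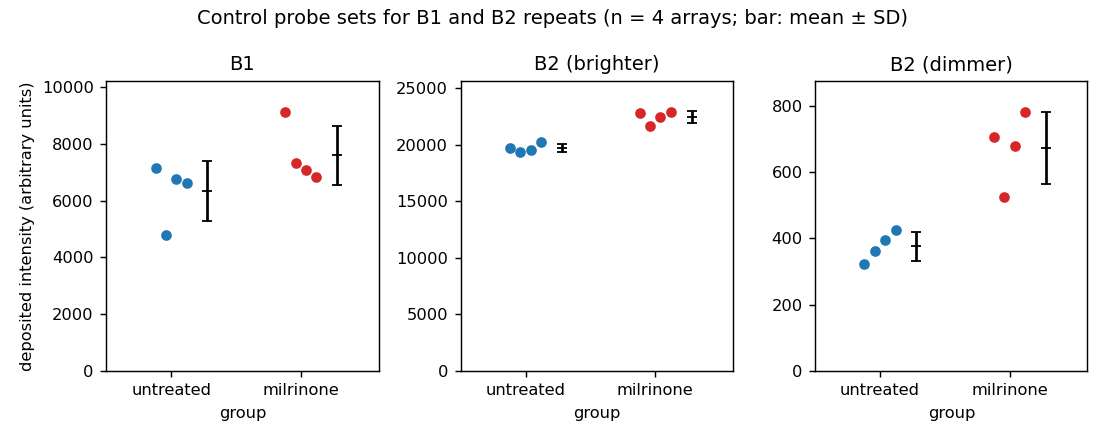
Deposited intensity of the control probe sets named for the B1 and B2 repeats on each array, untreated in blue and milrinone in red, with mean ± SD (n = 4) beside the points. The 4 milrinone arrays lie above the 4 untreated arrays for both B2 probe sets and overlap them for B1.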

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

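All tests weighed in this part were chosen after the results were seen, except the count of splits for the gene lists. Chance picks out about 1 in 20 groups of 4 arrays in this way, or 8.9 of the 178 groups examined, and 18 were found, each because 1 array lay far from the other 3 (ratio of its gap to the range of the group in parentheses). Untreated 1 was highest for Prkar2b (0.856), Hsd17b1 (0.892), Foxl2 (0.893), Rps3 (0.861) and Rps3a1 (0.866), and lowest for Plat (0.845) and for the mean of the stored messages (0.939). Untreated 3 was lowest for Kctd14 (0.976) and untreated 4 highest for the proteasome mean (0.865). Among milrinone arrays, replicate 1 was highest for H1f10 (0.857) and lowest for Brwd1 (0.842), and replicate 2 was lowest for Casp9 (0.839) and highest for Sgo1 (0.959). Milrinone 3 was highest for Ago3 (0.873). Milrinone 4 was highest for Tmx1 (0.892), Khdc3 (0.831) and Gdf9 (0.851) and lowest for Cnot6 (0.893).

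For the fall of the 19 probe sets, 1 of the 35 splits, the real grouping, called as many, and the highest of the others called 4. This argues against a random division of the arrays but does not exclude chance, because 1 of 35 is the smallest share possible. It also cannot tell milrinone culture from any other difference between the groups. RNA of cumulus, granulosa or theca cells in the untreated samples is a candidate source of the falls, and would make the ratio of untreated 1 to the other untreated arrays, each less the milrinone mean with empty cells as 0, similar to that of the 14 marker probe sets listed on all untreated and at most 2 milrinone arrays, which ran from 3.73 to 11.9 with a median of 5.11. Of the 19 called probe sets 5 lay at or above 3.73, among them Ctsl, Tmx1 and 1 probe set of Gja1. The cutoff of 3.73 is itself the ratio of a Gja1 probe set, and the next marker ratio was 4.47. Between them lay that called probe set of Gja1, at 4.14, and 1 with several symbols, at 3.93. Counts at this cutoff given further on rest on the same marker probe set. For the 14 below 3.73 the same source cannot be told apart from a loss in culture. The reason is that 2 of them belong to Gja1, itself a marker on the list, and Grem1, a gene of cumulus cells, had a ratio of 0.929. A low ratio for Pde7b (0.572), Myocd (1.01) or Kctd14 (1.13) therefore does not show that they are free of somatic RNA, and loss of oocyte transcripts during culture stays open as a hypothesis.

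For the gene lists, 30 of the 35 splits called at least as many as the real grouping, which called 2, and the highest of the others called 6, so chance cannot be excluded. With an estimated correlation, which was 0.598 for the ribosomal proteins against the preset 0.01, camera called 0 lists in the real grouping, and 1 had an unadjusted p under 0.05.

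The higher B2 signal in milrinone was set against dilution of oocyte RNA by other RNA in the untreated samples. Dilution would raise oocyte genes by as much, but over the 32 oocyte list genes with an intensity below 11871, away from the top of the range, the third quartile was 0.112, below the lower 95% limit of 0.44 for the dimmer B2 probe set. These genes were not matched to it in brightness. It had 322, 362, 395 and 425 on untreated 1 to 4, rising as the listed cumulus, granulosa and theca markers fell (42, 34, 30 and 27), and 524 to 782 in milrinone. A part for dilution is therefore not excluded. For the brighter one, with a lower limit of 0.0972 and a signal near the top of the range, dilution and a change in B2 RNA cannot be told apart. Scaling alone would move probe sets of similar brightness alike, and the difference of the dimmer probe set lay at percentile 99.9 among 3063 of them. For the dimmer one, cross-hybridisation, RNA integrity and a change in B2 RNA or in transcripts carrying it stay open and were not tested.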

How the results depend on the processing

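The 3 added alternatives were chosen after the data were seen. Other pseudocounts, quantile or median scaling, other filters on dim probe sets, eBayes without a trend and a 1.5-fold minimum gave 17 to 21 changed probe sets, all falling. Changed probe sets numbered 50 (48 falling) with centring on ribosomal proteins, which moved the median difference of all tested probe sets from 0.06 to 0.30, 106 (97 falling) with array weights, 9 at an adjusted p under 0.01, 11 without _x_ and _s_ probe sets, 85 (83 falling) without untreated 1 and 4, 12 among probe sets listed on all 8 arrays (fewer were tested) and 205 (196 falling) with empty cells at 0. Leaving out each array gave 9 (milrinone 3) to 69 (untreated 1), with shares falling from 83.3% (15 of 18 without untreated 3) to 100%. Called lists numbered 2 to 5 on leaving out each array, 4 without untreated 1 and 4, 5 with empty cells at 0, and 0 with an estimated correlation or with fry. The cause of these differences was not tested. With the replicate number as a block, 13 probe sets were called, all among the 19. Same-numbered arrays deviated with correlations of 0.03, -0.20, -0.02 and -0.27, which give no sign that the numbers pair the samples. With 4 pairs, and with untreated 1 and 4 standing apart, pairing is not excluded. Over the named genes, 1457 values under alternatives kept direction and side of the threshold, 39 fell short of it, 9 newly passed and 25 turned direction. For the lists, by the direction of the camera test, these numbers were 276, 0, 14 and 10, and the median had the other sign in 41 of 300. No value that turned passed the threshold in either setting. With quantile normalization Gdf9 became 0.0019 and Hprt -0.015, and with centring on the median Mos became -0.024 and Hprt -0.013. With centring on ribosomal proteins Kdr became 0.082, Astl 0.025, Psmd14 0.076, Dnmt1 0.013, Gdf9 0.18, Zp3 0.16, Dicer1 0.17 and the oocyte list 0.24. With array weights Kdr became 0.021, Tek -0.10 and Hprt -0.054, and the tests of oxidative phosphorylation (median 0.0054) and cell cycle control (0.069) turned. Without untreated 1 and 4 Kdr became 0.047, Tek -0.13, Plat -0.0094 and Hprt -0.054, and the tests of oxidative phosphorylation (0.064) and cell cycle control (0.014) turned. So did cell cycle control (0.062) without _x_ and _s_ probe sets and the oocyte list (0.011) with empty cells at 0. Leaving out each array gave -0.041 to 0.055 for Mos, -0.027 to 0.098 for Plat, -0.043 to 0.24 for Tek and -0.031 to 0.058 for Hprt, and medians of -0.0067 to 0.074 for stored messages, -0.030 to 0.072 for oxidative phosphorylation and -0.025 to 0.051 for the oocyte list, whose tests turned without at least 1 array. Kctd14, Pde7b, Myocd, Zeb1, Grem1 and Synpo passed under each alternative that gave them a value, while 1 probe set of Dsp did so under 12 of 19 (the other under 21 of 21), Tmx1 under 10 of 22 and Pdia6 under 9 of 22. Signal over background limits dim probe sets, whose empty cells give no bound.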

Other observations

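Of the tests in this part, the odds ratio within 10 classes of untreated level was set out before its value was seen, and the others were chosen after the results. Many probe sets were listed in only 1 of the groups. There were 212 listed on 4 of 4 untreated and 0 of 4 milrinone arrays, and 15 with the reverse, 227 in all, against at most 106 in any other split of the 8 arrays into 4 and 4. Leaving out untreated 1 gave 227 and 25, but this loosens the rule, so neither count could have dropped, whatever that array held. The brightest of the 212 include Cyp11a1, the retinaldehyde dehydrogenase gene Aldh1a1, the galectin gene Lgals1 and Sparc, all highest on untreated 1. The ratio of untreated 1 to the other untreated arrays, each less the milrinone mean with empty cells as 0, lay at or above the lowest marker ratio of 3.73 for 92 of the 212 and below it for 120. The 92 include marker probe sets that define this range, such as those of Cyp11a1 and Star, which lie in it by construction. The brightest of the 120 were the cyclin gene Ccnd2 at 1319 ± 389 (SD, n = 4), the serum amyloid gene Saa3 at 1164 ± 966 (SD, n = 4) and the lysozyme gene Lyz1 at 1069 ± 1180 (SD, n = 4). Lyz2, Col1a1 and the endothelial genes Eng, Esam and Egfl7 were also among them, so a ratio below that of the markers does not exclude RNA of other cell types. Prkar1b at 324 ± 28.9 (SD, n = 4) and the translation initiation factor gene Eif3a at 318 ± 67.4 (SD, n = 4) were among the 120 too. Ccnd2 is also known from granulosa cells, and another probe set of Eif3a was listed on all 8 arrays. The 15 listed only in milrinone were dim and include Nodal, a ligand of the TGF-beta family, at 61.9 ± 2.41 (SD, n = 4), Bcl10, a signalling adaptor gene, at 101 ± 8.20 (SD, n = 4) and Cox6a2, a subunit of cytochrome c oxidase, at 280 ± 54.5 (SD, n = 4), whose brighter probe set was listed on all 8 arrays and differed by 0.47 without passing (limma adjusted p = 0.479).

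Without untreated 1, more genes fell. They include the fatty acid desaturase gene Scd2 (log2 difference -3.46, adjusted p = 0.00146), the collagen lysyl hydroxylase gene Plod2 (-2.89, adjusted p = 0.00311), Creb1, the cAMP response element binding protein (-1.06, adjusted p = 0.0148, while its brightest probe set differed by -0.03 over all 8 arrays), Eif3a (-0.96, adjusted p = 0.0325) and the RNA helicase gene Dhx9 (-0.90, adjusted p = 0.0349). The gene that rose was Slco4c1, a transporter gene (0.82, adjusted p = 0.0489). These genes were named after their values were seen. Of the 68 probe sets that fell, which include the 19, 47 had a ratio at or above the lowest marker ratio of 3.73 and 21 lay below it. Scd2 (6.47), Plod2 (5.15) and Creb1 (4.04) were in that range, and Dhx9 (2.02) and Eif3a (0.665) below it. RNA of cumulus, granulosa or theca cells is thus a candidate source of many of these falls.

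Probe sets without a gene in the annotation were examined because repeat transcripts could be among them. Of those listed on at least 3 untreated arrays, 94 of 1107 (8.49%) were empty on all milrinone arrays, against 609 of 17503 (3.48%) with a gene (one-sided Fisher exact p = 8.9e-14, probe sets not being independent). This may reflect their lower signal in part, since the odds ratio was 2.57 overall and 1.55 (95% interval 1.22 to 1.97) within 10 classes of untreated level, so level in these classes accounts for some of it and not all. In the reverse direction, 26 of 984 (2.64%) listed on at least 3 milrinone arrays were empty on all untreated arrays, against 60 of 16159 (0.371%) with a gene, an odds ratio of 7.28 overall and 3.43 (2.12 to 5.56) within 10 classes of milrinone level. The excess of empty cells among unnamed probe sets thus lay in both directions and is not specific to milrinone, although a loss of some of them is not excluded. The median difference of tested probe sets was 0.07 without and 0.06 with a gene.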
